A study of Mus musculus with 16 samples.

How the data were processed

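RNA from mouse hearts was measured in 2 experiments prepared with different library kits, as Ion Total RNA-Seq libraries in experiment A and stranded Illumina TruSeq libraries in experiment B, per the labels' protocols. The series' design text names an Illumina instrument without setting the experiments apart. Of 16 labelled samples 15 had values; a further Cre+ library of experiment B was not part of the study per the series' design text and was not analysed here. The genome build mm10 and the tools STAR 2.6.0c and DESeq are named in the submitters' processing notes, with no role and no assignment to an experiment. The annotation, the counting tool and its strand setting are not given in the sources used here.

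For experiment A the authors deposited estimated counts per gene that need not be whole; 26.5% of the gene values above 0 are whole. The same deposited table holds rows per exon, used here only for Cap2, and rows per transcript, whose values run from 0 to 1 and were not used for tests. The authors' deposited comparison for experiment A holds a mean normalized signal per gene, log2 fold changes and p-values, with column names as DESeq2 writes them, per the file headers. For experiment B the authors deposited normalized read counts in whole numbers, a score here because their normalization is not stated. Since the values are whole after normalization and skip no whole number from 1 to 100 in any library, reads could not be recovered from them and no count test was run on experiment B. The depth behind the experiment B values is therefore unknown.

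Genes were named, placed and annotated by their Ensembl identifier with GENCODE M21, which uses the same build; 36308 of 38087 identifiers of experiment A and 54165 of 54232 of experiment B were found in it. Estimated counts of the gene rows were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, robust quasi-likelihood test). The standard error of an edgeR fold change is its size divided by the square root of the F statistic. Values of experiment A are given as CPM. Group means, their SD and the plotted values are scaled to the TMM-adjusted total of the genes tested, and the values per library of Myl7 and Hbb-bs and the exonic blocks of Cap2 to the unadjusted library total. Normalized counts of experiment B with a mean of at least 10 were tested with limma 3.58.1 (robust limma-trend) on log2(value + 1) with sex as a term; fold changes on this scale understate the change of genes with low values. P-values were adjusted by Benjamini-Hochberg, and a gene with an adjusted p under 0.05 is termed called. The labels give each analysed library of both experiments a number of its own beside the replicate number but do not say that these stand for separate animals; if they do not, p-values measure only the spread between these samples, which may be technical.

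The tested gene lists, 30 in all, cover pathways of heart muscle and markers of other cell types. They were fixed before the data were examined, as were the tests, the main settings, most alternatives and the rule for the genes named. Lists with at least 4 tested members were tested with camera (correlation of 0.01), and again with camera's estimated correlation and with fry. This left 28 lists in experiment A and 29 in experiment B. With the correlation of 0.01, other splits of the libraries called up to 10 lists in experiment A and 22 in experiment B. The real groups gave 8 and 14, so a set called only this way is not set apart from chance. The genes named are Cap2, Cap1 and 8 fixed cardiac and MRTF/SRF genes, and the 8 largest rises and falls with an adjusted p under 0.05. The latter needed groups that do not overlap, a mean of at least 1 CPM (A) or 50 normalized counts (B) and no predicted or clone name. Of each described list, up to 4 members with the smallest p are named, and up to 10 genes called in both experiments; other called members are named where few were called. Some genes that this rule names or that a test used are not reported here, though counts include them. Overlaps of calls were tested with Fisher's exact test among genes tested in both.

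Replicate libraries of a group in experiment A differed by more than sampling noise, with a chi-square per gene of 10.7 to 29.1 on rounded counts. In experiment B the same figure was 25.6 to 290 on the normalized values. It cannot be set against sampling noise there, since the depth is unknown. No library was counted as a repeat of another. Self-tests on simulated data changed 200 genes. In the design of experiment A, 66.3% of the tested 2-fold changes and 97.9% of the 4-fold changes were recovered among 16038 genes, and in that of experiment B 14.3% and 62.5% among 11990 genes. Unchanged genes made up 14 of the 172 calls in the first simulation and 4 of the 78 calls in the other. The simulations drew each gene independently, without sex or library-wide effects, so these shares need not hold for the real libraries. Alternatives covered normalization, DESeq2 1.42.0 for experiment A, filters, pseudocounts of 0.5 and 10, the sex term, a replicate block and leaving out each library in turn.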

Results

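Heart RNA was sequenced in mice lacking CAP2, a cyclase-associated protein that binds actin monomers and promotes the turnover of actin filaments. The study title places the work in CAP2-dependent dilated cardiomyopathy and in signalling through MRTF and SRF, a co-activator and transcription factor pair that responds to the level of free actin. Experiment A compared hearts of 86-week-old females, 3 wild-type and 3 with both copies of Cap2 disrupted (CAP2 −/−). Experiment B compared hearts of 13-week-old mice homozygous for the loxP allele, 5 without Cre (3 females and 2 males, here the controls) and 4 with Cre under the cardiomyocyte promoter Myh6 (3 females and 1 male, here Cre+). The Cre transgene and the loss of Cap2 therefore came together in experiment B. The libraries of experiment A held 10750175 to 27440478 estimated counts. In experiment B the normalized counts of nuclear genes summed to 3815980 to 4044523 per library. Mitochondrially encoded genes made up 30.4% to 69.5% of the total in the controls and 23.0% to 52.7% in Cre+.

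Experiment A asked which transcripts differ in the aged heart without CAP2. Cap2 itself (ENSMUSG00000021373, chromosome 13, 46501848 to 46650281, mm10) fell from 214 ± 15.7 CPM in wild type to 12.2 ± 3.91 in CAP2 −/− (SD, n = 3 each), with a log2 fold change of -4.13 (SE 0.20, edgeR adjusted p = 1.00e-07). The residual reads were spread over the gene. In the 13 exonic blocks with at least 50 wild-type reads, the CAP2 −/− libraries held 1.40% to 7.58% of the wild-type level. The related gene Cap1 gave a log2 fold change of 0.08 (SE 0.12, adjusted p = 0.893). Of 16297 genes tested, 220 passed an adjusted p of 0.05, 137 higher and 83 lower in CAP2 −/−. Groups did not overlap for 2542 of the 16297 genes, the 220 included, where chance gives 10% with 3 against 3 libraries. The count was 144 without wild-type replicate 3, 137 without CAP2 −/− replicate 2 and 126 without CAP2 −/− replicate 3.

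Among the genes with the largest rises in CAP2 −/− hearts, predicted and clone names aside, were those of a cardiac stress peptide and of proteins of the actin cytoskeleton. Nppa, the atrial natriuretic peptide gene (chromosome 4, 148000722 to 148002079), rose 44.7-fold, from 95.4 ± 21.3 to 4265 ± 399 CPM (log2 fold change 5.48, SE 0.18, adjusted p = 3.07e-10). Acta1, skeletal alpha-actin (chromosome 8, 123891769 to 123894751), rose by log2 4.65 (SE 0.35, adjusted p = 0.00349). Acta2, smooth muscle alpha-actin (chromosome 19, 34241090 to 34255590), rose 23.5-fold (log2 4.55, SE 0.43, adjusted p = 0.0174). The myosin light chain gene Myl9 (chromosome 2, 156775420 to 156781658) rose 23.3-fold (log2 4.54, SE 0.18, adjusted p = 4.81e-09). Comp, a cartilage matrix protein gene (chromosome 8, 70373558 to 70382066), rose by log2 3.80, the metalloproteinase gene Adamts8 9.33-fold, the growth factor gene Gdf6 9.09-fold and Tent5b 7.74-fold. The largest falls besides Cap2 were in the phosphodiesterase gene Pde11a (chromosome 2, 75989141 to 76338774), at log2 -4.14 (SE 0.37, adjusted p = 9.75e-06), in Nags (-2.69) and in Epn3 (-2.45). Kcnk1, a potassium channel gene, fell by 2.31 on the log2 scale, Retnla by 2.06, the transporter gene Abca4 by 1.98 and Cubn by 1.89. Nppb, the B-type natriuretic peptide gene (chromosome 4, 147985788 to 147987205), was at 86.0 ± 42.3 CPM in wild type and 417 ± 22.8 in CAP2 −/− but missed the threshold (log2 2.27, SE 0.42, adjusted p = 0.119). Srf (log2 0.19, adjusted p = 0.602) and the myosin heavy chain genes Myh6 (0.024, adjusted p = 0.967) and Myh7 (0.26, adjusted p = 0.459) were not called.

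Single libraries decided some of these calls. The adjusted p of Nppb was 0.0124 without wild-type replicate 1, 1.54e-06 without wild-type replicate 2 and 5.46e-06 with DESeq2, in a range of 1.54e-06 to 0.356 over all alternatives. Acta2 missed the threshold without wild-type replicate 3, CAP2 −/− replicate 2 or CAP2 −/− replicate 3 (adjusted p = 0.103, 0.0959 and 0.0729), and Cubn without wild-type replicate 3 (0.0602). Among the fits without 1 library, Nags kept its call only without wild-type replicate 3, and its adjusted p reached 0.153 without CAP2 −/− replicate 3. The actin genes, and likewise Myh6 and Myh7, are near-identical paralogs, and Nppa overlaps the antisense gene Gm13054, so how reads were divided among them is uncertain.

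**Figure D1:**
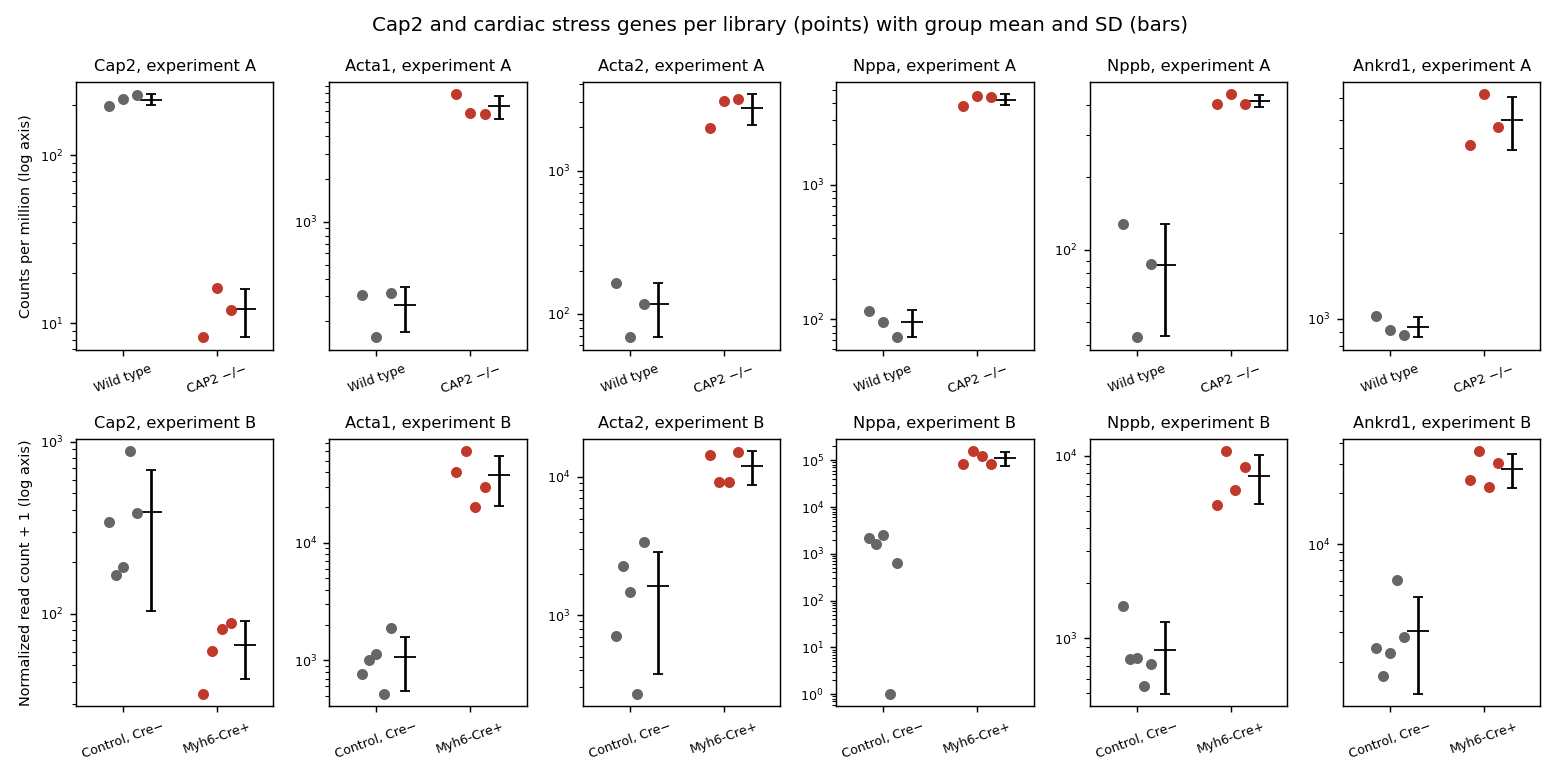
Values per library of Cap2, Acta1, Acta2, Nppa, Nppb and Ankrd1 in experiment A (upper row, CPM, log axis) and experiment B (lower row, normalized read count + 1, log axis), with points for libraries and bars for the group mean and SD; the controls of experiment B have no bar for Nppa, where 1 control is listed at 0. Cap2 was lower and the other genes were higher in every CAP2 −/− or Cre+ library than in every control of the same experiment, for example Nppa at 80982 to 155401 in Cre+ and 0 to 2511 in the controls.

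Of the 27 genes in the list of MRTF/SRF cytoskeletal targets, 8 rose and none fell in experiment A (12 rose adjusted over the list alone). Besides Myl9, Acta1 and Acta2 these were Actc1, cardiac alpha-actin (log2 1.11, SE 0.11), Pdlim7 (1.37, SE 0.17), Tpm1, a tropomyosin (0.68, SE 0.10), Cnn2, a calponin (0.63, SE 0.13), and Ccn2, a matricellular growth factor (chromosome 10, 24595442 to 24598683; 1.94, SE 0.25, adjusted p = 0.0109). The list was higher as a set (camera adjusted p = 5.85e-32; adjusted p = 0.0363 with an estimated correlation). Among 14 cardiac stress and fetal genes, 4 rose and none fell (11 rose adjusted over the list alone). They were Nppa, Acta1, the cofactor gene Ankrd1 (chromosome 19, 36111961 to 36120099; log2 2.42, SE 0.14) and Uchl1 (1.04, SE 0.17), and the set was higher (camera adjusted p = 9.92e-44; adjusted p = 0.00843 with an estimated correlation). The 6 tested atrial markers were higher as a set (camera adjusted p = 5.19e-26, and 0.00843 with an estimated correlation). The 2 members called were Nppa and the light chain gene Myl1 (chromosome 1, 66924295 to 66945404, log2 1.45, SE 0.17). Adjusted over the list alone, 4 atrial markers rose and 1, Stard10, fell. DESeq2 also called the atrial markers Bmp10 (adjusted p = 0.00819) and Myl4 (0.0410). The atrial light chain gene Myl7 was at 1.09 to 1.70 CPM in the 6 libraries. Ccn2 missed the threshold without CAP2 −/− replicate 1 or 3 (adjusted p = 0.0508 and 0.0606), and Cnn2 without wild-type replicate 2 or 3 or CAP2 −/− replicate 2 or 3 (highest adjusted p = 0.107).

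Some matrix genes, led by Comp and Thbs4, rose in CAP2 −/− hearts, and the fatty acid oxidation genes Acaa2 and Cpt2 fell. Of 30 extracellular matrix and fibrosis genes, 10 rose and none fell (19 rose adjusted over the list alone). Besides Comp these included Thbs4, a thrombospondin (chromosome 13, 92751590 to 92794818; log2 2.67, SE 0.20), the growth factor gene Tgfb2 (2.10, SE 0.17) and the collagen gene Col8a1 (1.31, SE 0.16). The set had a camera adjusted p of 5.52e-51, against an adjusted p of 0.0684 with an estimated correlation. Of 12 fibroblast markers, 2 rose, Mfap5 (log2 1.11, SE 0.16) and Wif1 (1.69, SE 0.33), and 6 rose adjusted over the list alone (camera adjusted p = 0.000304; adjusted p = 0.0762 with an estimated correlation). Of 25 fatty acid oxidation genes, 2 fell, Acaa2 (log2 -0.52, SE 0.11) and Cpt2 (-0.48, SE 0.10), and 10 fell adjusted over the list alone. The set was lower (camera adjusted p = 1.61e-06; adjusted p = 0.152 with an estimated correlation). Acaa2 missed the threshold without wild-type replicate 3 or CAP2 −/− replicate 2 or 3 (highest adjusted p = 0.131), Wif1 without wild-type replicate 1 or 3 or CAP2 −/− replicate 3 (0.113), and Cpt2 without any library except CAP2 −/− replicate 1 (0.138).

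Skeletal muscle markers were higher as a set in experiment A (camera adjusted p = 0.000535, against 0.147 with an estimated correlation). Myl1, which is also on the atrial list, was the 1 member of 9 called in edgeR (2 rose adjusted over the list alone). DESeq2 also called Tnnt3 (adjusted p = 0.0474). Interferon response genes were higher as a set (camera adjusted p = 0.00352; adjusted p = 0.675 with an estimated correlation) with 0 of 15 called in edgeR, over all genes or adjusted over the list alone. Examples were Ifit2 (log2 0.62, adjusted p = 0.159) and Isg15 (0.71, adjusted p = 0.274), and Ifit2 passed without CAP2 −/− replicate 1 (adjusted p = 0.0433, in a range of 0.0433 to 0.622 over all alternatives).

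The remaining lists were not called in experiment A, with camera adjusted p values of 0.0523 to 0.981. Among 18 contractile genes of adult cardiomyocytes 2 rose, Actc1 and Tpm1 (2 rose and 1 fell adjusted over the list alone). Of 20 Z-disc and M-band genes, Pdlim5 rose (log2 0.82, SE 0.11) and Myot, which encodes myotilin, fell (-1.42, SE 0.15), with the same counts adjusted over the list alone. Dstn, an actin-depolymerizing factor, rose 2.13-fold as the 1 called of 26 actin filament regulators (1 rose and 1 fell adjusted over the list alone). Kcnip2 (log2 0.83) was the 1 called of 25 ion channel and conduction genes (2 rose and 3 fell adjusted over the list alone). Ier3 (0.84) was the 1 called of 16 immediate early genes and Krt18 (1.53) the 1 called of 7 mesothelial markers (1 rose and 1 fell adjusted over the list alone in each). In edgeR no member passed over all genes among nuclear oxidative phosphorylation, glycolysis, integrated stress response and endoplasmic reticulum chaperone genes. The same held for heat shock, cell cycle and circadian clock genes. It also held for endothelial, smooth muscle and pericyte, macrophage, lymphocyte, erythroid, fat cell and Schwann cell markers. Some members of the glycolysis, endothelial, smooth muscle and pericyte and fat cell lists passed in the authors' deposited comparison. Adjusted over the list alone, 3 glycolysis genes, 1 endothelial marker and 1 fat cell marker fell, 1 heat shock gene rose, and 2 smooth muscle and pericyte markers rose and 1 fell. The median, mean and test differed in sign for 5 of these lists, namely Z-disc and M-band (median log2 0.022, mean -0.041, test lower), smooth muscle and pericyte (-0.14, 0.040, lower), erythroid (0.24, 0.33, lower), clock (0.099, -0.026, lower) and mesothelial (-0.082, 0.044, lower). Ier3 missed the threshold without wild-type replicate 1 or 3 or CAP2 −/− replicate 3 (highest adjusted p = 0.0984), and Krt18 without any 1 of the 6 libraries (0.159).

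Experiment B asked which transcripts differ in young hearts whose cardiomyocytes carry Cre. Cap2 fell from 391 ± 288 normalized counts in the controls (SD, n = 5) to 65 ± 24.2 in Cre+ (SD, n = 4), with a log2 fold change of -2.22 on the log2(value + 1) scale (SE 0.36, limma adjusted p = 0.0161). Every Cre+ library, at 33 to 87, lay below every control. Cap1 gave 0.23 (SE 0.31, adjusted p = 0.681). Of 12141 genes tested, 228 passed, 115 higher and 113 lower in Cre+. Groups did not overlap for 1052 of the 12141 genes, 205 of the 228 among them, where chance gives 1.59%. The split depended on the scaling, with 151 higher and 67 lower after TMM scaling and 211 higher and 124 lower after quantile normalization, and on single libraries, with 210 higher and 485 lower without Cre+ replicate 1 and 34 higher and 14 lower without control replicate 1. The adjusted p of Cap2 was 0.0687 without control replicate 1, 0.0922 without Cre+ replicate 4 and 0.246 with the level of atrial markers as a covariate, in a range of 0.00217 to 0.246 over all alternatives. The count of genes was 48, 45, 82, 403 and 525 without control replicates 1 to 5, 695, 39, 48 and 57 without Cre+ replicates 1 to 4, 33 with the mitochondrial share as a covariate and 16 with the atrial markers.

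The genes that rose most in Cre+ hearts included troponins and other proteins of fast skeletal muscle beside stress genes. Tnnt3, fast skeletal troponin T (chromosome 7, 142498836 to 142516009), rose from 6.2 ± 4.15 to 829 ± 892 normalized counts (log2 5.89, SE 0.65, adjusted p = 0.00132). Tnni2, fast skeletal troponin I (chromosome 7, 142441808 to 142444410), rose by log2 4.89 (SE 0.54) and Casq1, skeletal calsequestrin (chromosome 1, 172209894 to 172219868), by 4.23 (SE 0.38). Acta1 rose 35.5-fold (log2 5.15, SE 0.42, adjusted p = 0.000395) and Adamts8 (chromosome 9, 30942562 to 30963838) 52.9-fold (log2 5.73, SE 0.85, adjusted p = 0.0103). Tent5b (log2 4.77) and the nicotinamide riboside kinase gene Nmrk2 (4.01) were also among the largest rises. Among the largest falls were the potassium channel subunit gene Kcnv2 (chromosome 19, 27322588 to 27337179; log2 -3.77, SE 0.66), the ephrin gene Efnb3 (chromosome 11, 69554092 to 69560205; -3.34, SE 0.36), Myot (-3.12, SE 0.49) and Ogdhl (-3.08, SE 0.29). Pfkfb1 fell by 3.07 on the log2 scale, Adamts7 by 2.46 and Cpeb3 by 2.26. Nppb rose 8.97-fold (adjusted p = 0.000963), Myh7, the beta myosin heavy chain (chromosome 14, 54970684 to 54994626), 5.93-fold (adjusted p = 0.0203), Acta2 9.94-fold (adjusted p = 0.0294) and Ccn2 10.3-fold (adjusted p = 0.0278). Nppa was at 83376, 155401, 123134 and 80982 in Cre+ replicates 1 to 4 and at 2129, 1629, 2511, 0 and 628 in control replicates 1 to 5, with an adjusted p of 0.0742 over all libraries. Myh6 (log2 0.05, adjusted p = 0.936) and Srf (0.58, adjusted p = 0.184) were not called.

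Many of these calls in experiment B depended on single libraries or on a setting. Nppa passed without control replicate 4, listed at 0 (log2 6.12, adjusted p = 3.47e-06), without control replicate 5 (8.45, 0.0457) and without Cre+ replicate 1 (8.07, 0.0366). It also passed with females only (adjusted p = 5.38e-05), after quantile normalization (0.0364) and with a pseudocount of 10 (log2 7.10), in a range of 3.47e-06 to 0.736 over all alternatives. Acta2 missed the threshold without any 1 of control replicates 1 to 3 and Cre+ replicates 2 to 4 (highest adjusted p = 0.160). Myh7 did so without control replicates 1 or 2 or Cre+ replicates 2, 3 or 4 (0.0974), and Ccn2 without control replicates 2 or 3 or Cre+ replicates 2, 3 or 4 (0.158). Tent5b missed it without control replicate 2 or Cre+ replicates 2, 3 or 4 (0.0799), Kcnv2 without control replicates 1, 2 or 3 or Cre+ replicate 2 (0.0809), Myot without control replicate 1 or Cre+ replicates 3 or 4 (0.0794), and Adamts8 without Cre+ replicate 4 (0.0690). With no filter on low values Acta2, Ccn2, Adamts8 and Myl9 missed it as well (adjusted p = 0.0656, 0.0656, 0.0534 and 0.0919).

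Members of the stress, cytoskeletal and matrix lists rose in Cre+ hearts, and Acot1, Ucp3 and Decr1 of the fatty acid oxidation list fell. Of 15 cardiac stress and fetal genes, 8 rose and none fell (13 rose adjusted over the list alone), among them Acta1, Nmrk2 (chromosome 10, 81198170 to 81202051), Ankrd1 (log2 3.43, SE 0.32) and Nppb. This was the 1 list whose call held with an estimated correlation (camera adjusted p = 3.57e-19; adjusted p = 0.0461 with an estimated correlation). Of 27 MRTF/SRF cytoskeletal targets, 5 rose, namely Acta1, Acta2, Ccn2, Pdlim7 (log2 2.44, SE 0.39) and Myl9 (3.90, SE 0.72), and 15 rose adjusted over the list alone (camera adjusted p = 1.87e-11; adjusted p = 0.246 with an estimated correlation). Of 30 extracellular matrix and fibrosis genes, 14 rose, and 28 rose adjusted over the list alone (camera adjusted p = 1.00e-25; adjusted p = 0.246 with an estimated correlation). Examples were Thbs4 (log2 3.60, SE 0.47), Tgfb2 (2.81, SE 0.39), tenascin C, Tnc (3.01, SE 0.48), and the protease inhibitor gene Timp1 (3.74, SE 0.62). Of 25 fatty acid oxidation genes, 3 fell, and 18 fell adjusted over the list alone (camera adjusted p = 1.51e-09; adjusted p = 0.246 with an estimated correlation). They were Acot1 (log2 -1.76, SE 0.29), Ucp3 (-1.87, SE 0.39) and Decr1 (-1.15, SE 0.24). Calls were lost without any 1 of control replicates 1 to 3 and Cre+ replicates 2 to 4 for Decr1 (highest adjusted p = 0.160), without control replicates 1 or 2 or Cre+ replicates 2, 3 or 4 for Myl9, Timp1 and Ucp3 (0.169, 0.0842 and 0.172), and without control replicates 2 or 3 or Cre+ replicates 2, 3 or 4 for Acot1 (0.0842). Pdlim7 lost its call without control replicate 2 or Cre+ replicates 2, 3 or 4 (0.0893). Tnc did so without control replicate 2 or Cre+ replicates 2 or 3 (0.0642). Ucp3 and Decr1 also lost theirs after TMM scaling (0.0506 and 0.0738) and with females only (0.0805 and 0.0577).

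**Figure D2:**
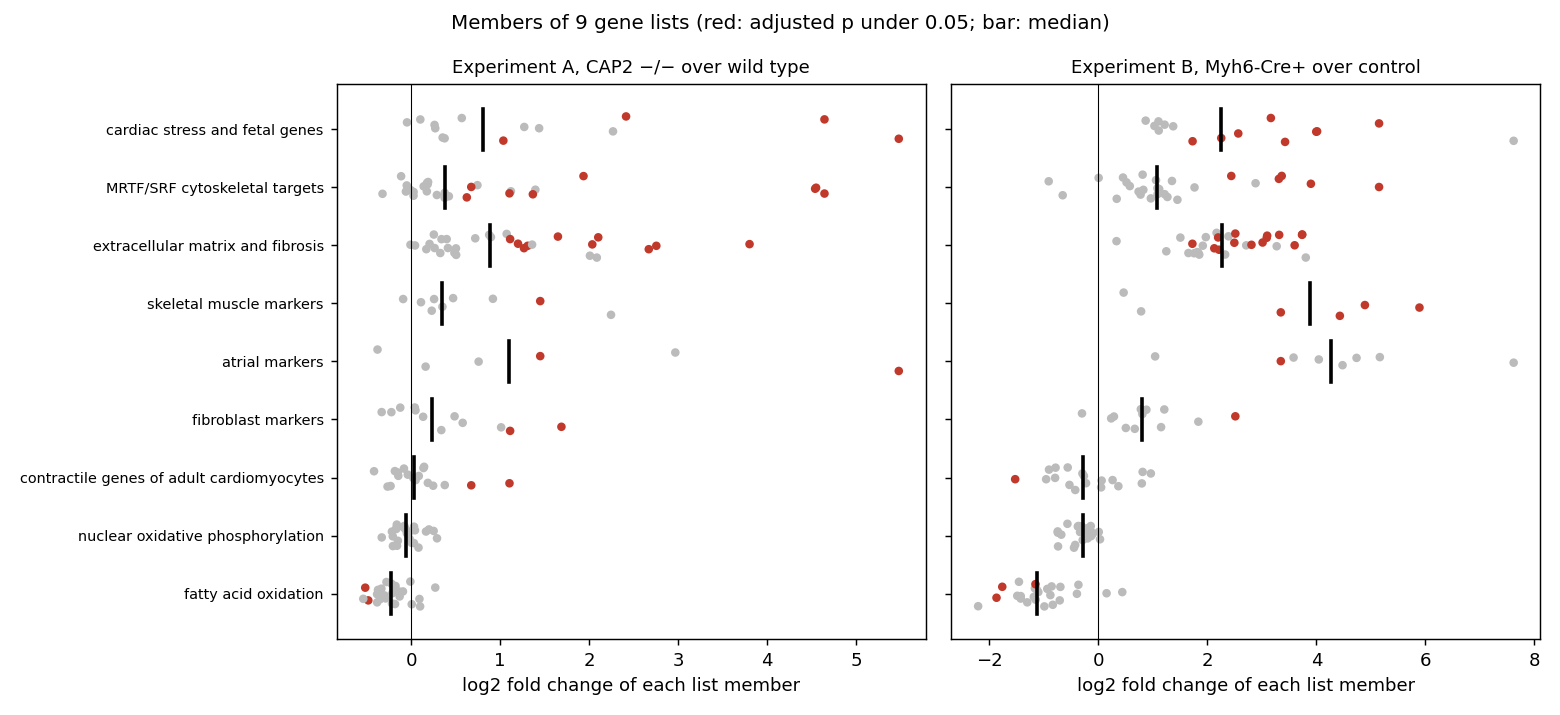
Log2 fold change of each tested member (points) of 9 gene lists in experiment A (left) and experiment B (right), with the list median as a bar and genes with an adjusted p under 0.05 in red. The medians of stress genes were 0.80 and 2.26 and those of matrix genes 0.89 and 2.27, while fatty acid oxidation genes had medians of -0.22 and -1.13.

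Tnnt3, Tnni2, Myl1 and Atp2a1 of the skeletal muscle list rose in Cre+ hearts. The atrial markers Myl7, Myl4, Sln and Mybphl were above all controls in 3 of the 4 Cre+ libraries and missed the threshold. Of 6 tested skeletal muscle markers 4 rose, Tnnt3, Tnni2, Myl1 (log2 3.35, SE 0.34) and the calcium pump gene Atp2a1 (4.43, SE 0.70). The same number rose adjusted over the list alone. The set had a camera adjusted p of 4.05e-08, against an adjusted p of 0.0872 with an estimated correlation. The fast myosin genes Myh1, Myh2 and Myh4 were at 0 to 3 normalized counts in every library. Atrial markers were higher as a set (camera adjusted p = 8.89e-07; adjusted p = 0.258 with an estimated correlation), with Myl1 the 1 called of 8 (2 rose adjusted over the list alone). Myl7 was at 105 in Cre+ replicate 1 and at 6996, 10677 and 17044 in Cre+ replicates 2 to 4, and at 21, 344, 3014, 16 and 58 in control replicates 1 to 5. The adjusted p was 0.209 for Myl7, 0.165 for Myl4, 0.265 for Sln and 0.222 for Mybphl, and without Cre+ replicate 1 it was 0.0342, 0.0195, 0.0318 and 0.0176. Atp2a1 lost its call without Cre+ replicates 2, 3 or 4 (highest adjusted p = 0.112).

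**Figure D3:**
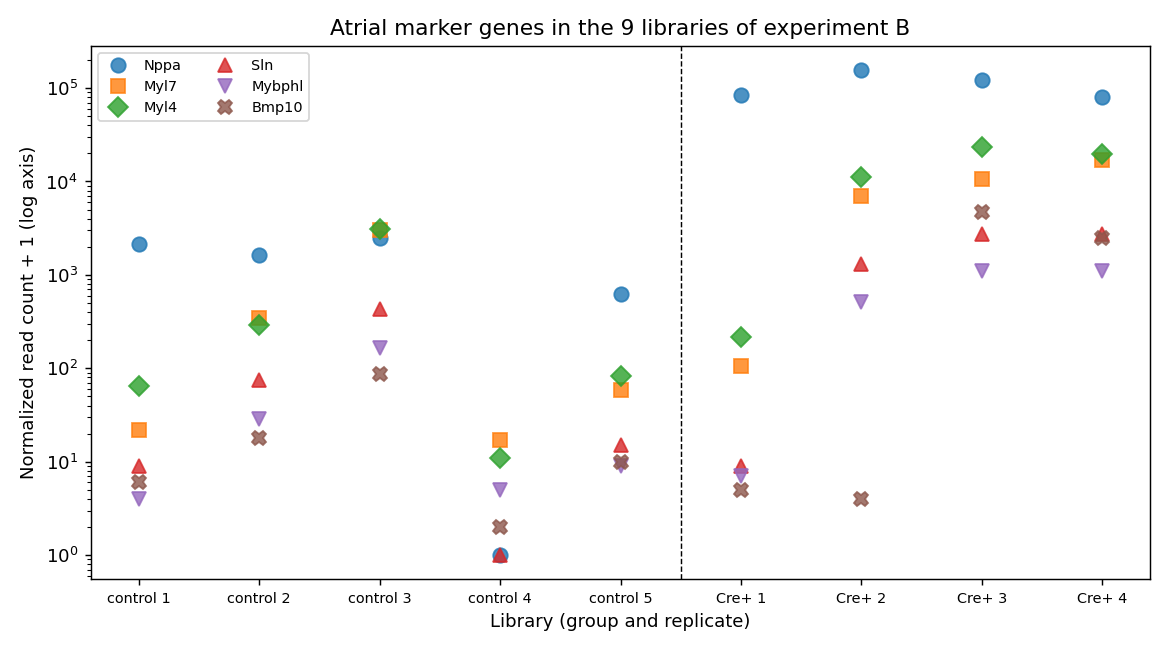
Normalized read count + 1 (log axis) of the atrial marker genes Nppa, Myl7, Myl4, Sln, Mybphl and Bmp10 in the 5 control and 4 Cre+ libraries of experiment B. Nppa was at 80982 or more in all 4 Cre+ libraries, while Myl7 was at 105 in Cre+ replicate 1 and at 6996 to 17044 in the others.

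The integrated stress response genes Mthfd2 and Pycr1, the immediate early genes Ier3 and Myc, the fibroblast marker Mfap5 and the mesothelial marker Krt18 rose in Cre+ hearts. Their lists had few called members, and no set call in the following lists held with an estimated correlation. Integrated stress response genes were higher (camera adjusted p = 7.62e-05; adjusted p = 0.246 with an estimated correlation) with 2 of 12 called, also adjusted over the list alone, the folate enzyme gene Mthfd2 (log2 2.68, SE 0.48) and the proline synthesis gene Pycr1 (2.73, SE 0.55). Immediate early genes were higher (adjusted p = 7.62e-05; adjusted p = 0.457 with an estimated correlation) with Ier3 (log2 1.76, SE 0.27) and Myc (2.01, SE 0.36) called of 16, and 3 adjusted over the list alone. Cell cycle genes were higher (adjusted p = 2.87e-05; adjusted p = 0.258 with an estimated correlation) with 0 of 12 called in limma and 4 adjusted over the list alone. Cdk1 was at log2 3.26 (adjusted p = 0.0598) and passed without control replicates 4 or 5 or Cre+ replicate 1 (0.0497, 0.0388 and 0.0323, in a range of 0.0284 to 0.704 over all alternatives). Of 12 fibroblast markers Mfap5 was called (log2 2.51, SE 0.51), and 5 rose adjusted over the list alone (adjusted p = 8.68e-05; adjusted p = 0.457 with an estimated correlation). Macrophage markers were higher (camera adjusted p = 0.000201, against 0.457 with an estimated correlation). In the main limma fit 0 of 12 were called, over all genes or adjusted over the list alone, for example C1qa at log2 1.14 (adjusted p = 0.158). C1qb passed with the replicate block in place of sex (log2 1.34, adjusted p = 0.0412). Of 8 mesothelial markers Krt18 was called (log2 3.81, SE 0.53), and 2 rose adjusted over the list alone (adjusted p = 3.09e-05; adjusted p = 0.357 with an estimated correlation). Z-disc and M-band genes were higher (adjusted p = 0.0224; adjusted p = 0.544 with an estimated correlation), with Synpo2l (log2 1.72, SE 0.26) and Flnc, filamin C (1.42, SE 0.31), rising and Myot falling of 20, and 3 rising and 1 falling adjusted over the list alone. Ion channel and conduction genes were lower (adjusted p = 0.0120; adjusted p = 0.457 with an estimated correlation), with Kcnv2 called of 24 and 6 falling adjusted over the list alone. Calls were lost without any 1 of control replicates 1 to 3 and Cre+ replicates 2 to 4 for Pycr1, Myc, Mfap5 and Flnc (highest adjusted p = 0.172, 0.107, 0.151 and 0.228), and without control replicates 1 or 2 or Cre+ replicates 2, 3 or 4 for Mthfd2 (0.110). Ier3 lost its call without control replicate 1 or Cre+ replicates 2 or 4 (0.0717) and Synpo2l without control replicate 2 or Cre+ replicates 2 or 4 (0.0716), while Flnc also lost it after TMM scaling (0.0552).

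The remaining lists were not called in experiment B. Among them Pln, phospholamban, fell (log2 -1.53, SE 0.30) as the 1 called of 18 contractile genes, and the channel regulator gene Abcc9 fell (-1.63, SE 0.36) as the 1 called of 12 smooth muscle and pericyte markers, each also the 1 adjusted over its list alone. No member passed over all genes among actin filament regulators, oxidative phosphorylation (nuclear and mitochondrial), glycolysis, chaperone, heat shock, interferon and clock genes, nor among endothelial, erythroid, fat cell and Schwann cell markers. Adjusted over the list alone, 1 glycolysis gene rose and 2 fell, 3 heat shock genes rose and 1 fell, and 4 clock genes fell. Glycolysis genes had a median log2 fold change of 0.11, a mean of -0.0081 and a test direction of higher. Pln and Abcc9 lost their calls without any 1 of control replicates 1 to 3 and Cre+ replicates 2 to 4 (highest adjusted p = 0.171 and 0.253) and after TMM scaling (0.0540 and 0.0595). Sex-linked genes, as a list not called, followed the labels in all 9 libraries, with Xist at 400 to 1830 in females and 1 to 5 in males. Lymphocyte markers in experiment B, and mitochondrial and sex-linked genes in experiment A, had too few tested members for a set test.

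The stress gene Ankrd1, Acta1 and the matrix genes Thbs4 and Tgfb2 rose, and Ogdhl and Efnb3 fell, in both experiments. These share no libraries and were normalized separately, so their calls were compared as lists. Among 11776 genes tested in both, 42 rose in both where 1.04 were expected of independent lists (Fisher's exact test, 2-sided p = 4.69e-59). Likewise 18 fell in both where 0.675 were expected (Fisher's exact test, 2-sided p = 2.10e-21). These 18 include Cap2, the gene targeted in both experiments. The test takes genes as independent units, which genes that change together are not. Its p-values therefore do not measure how far the overlap would repeat in other libraries. The genes called in both with the smallest p were Ankrd1, Myl1, Ogdhl, Efnb3, the predicted gene Gm11627, Casq1, Thbs4, Tgfb2, Acta1 and Uchl1. Ogdhl, which resembles a subunit of the oxoglutarate dehydrogenase complex (chromosome 14, 32322019 to 32348151), fell by 0.99 (SE 0.13) in experiment A and by 3.08 (SE 0.29) in experiment B on the log2 scale. Casq1 rose by 2.93 (SE 0.34) and 4.23 (SE 0.38), and Gm11627 by 4.79 (SE 0.41) and 2.99 (SE 0.36). Armc2 was the 1 gene called in opposite directions, at log2 1.07 (SE 0.14) in experiment A and -1.60 (SE 0.36) in experiment B. It was singled out after its values were seen. Independent lists would share 1.05 genes that rose in experiment A and fell in experiment B (Fisher's exact test, 2-sided p = 1), and 0 genes were called the other way round. Across the 11776 genes the log2 fold changes had a Pearson correlation of 0.416 and a Spearman correlation of 0.240, which are across genes and so not over independent replicates. The count of 60 shared genes was 22, 20, 33 and 95 without control replicates 1, 2, 3 and 5 of experiment B, and 18, 20 and 20 without Cre+ replicates 2, 3 and 4. Armc2 lost its call in experiment B without any 1 of control replicates 1 to 3 and Cre+ replicates 2 to 4 (highest adjusted p = 0.169) and after TMM scaling (0.0702).

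**Figure D4:**
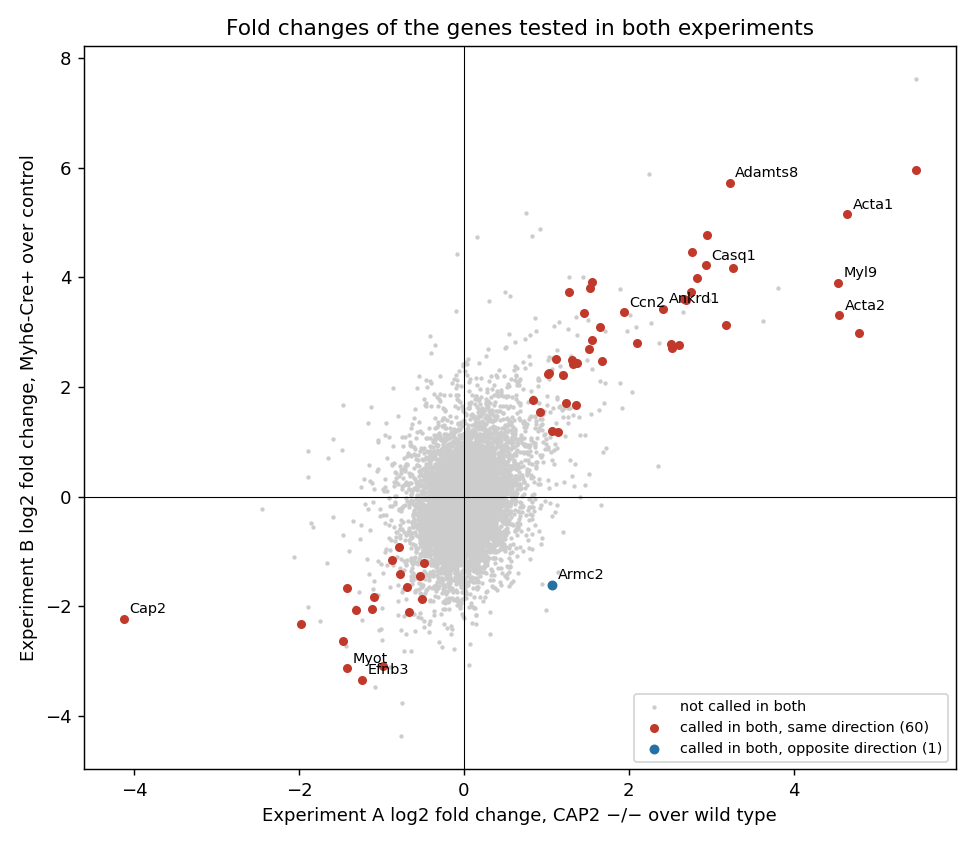
Log2 fold change in experiment A (x axis) against experiment B (y axis) for the 11776 genes tested in both, with the 60 genes called in both in the same direction in red and Armc2, called in opposite directions, in blue. Acta1 (4.65 and 5.15) lies at the upper right and Cap2 (-4.13 and -2.22) at the lower left.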

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

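Of the tests in this part, the amount of Nppa per Myl7, the ratios among the other atrial markers, the covariate fit on atrial markers, the comparison of the control males with the Cre+ male, the simulated value without a sex effect and the summed rows behind the authors' deposited table were chosen only after the results they address had been seen. In the 2 groups of experiment B, 134 sets of values were searched for a library far from the rest of its group, as the gap to the nearest library over the whole range of the group. Chance marks about 1 in 20, or 6.7 here, and 12 were marked, so single marks carry little weight. In Cre+ replicate 1 the ratio was 0.840 for Myl4, 0.868 for Sln, 0.850 for Mybphl and 0.849 for Atp2a1, all low, 0.867 for Cpeb3, which was high, and 0.869 for the second principal component. In control replicate 4 it was 0.823 for Nppa and 0.828 for Pdlim7, both low, and 0.762 for the first principal component. Single marks were Ogdhl in Cre+ replicate 3 (0.892, low), Atp2a1 in control replicate 2 (1, that library being at 0 and the other controls at 1 normalized count) and the total of nuclear genes in control replicate 3 (0.730, low). In limma 0 of 12141 genes had an interaction of genotype and sex past an adjusted p of 0.05, with 504 at an unadjusted p under 0.05 and a single Cre+ male behind that test.

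Atrial markers differed between Cre+ libraries, with Cre+ replicate 1 within the range of the controls for Myl7, Myl4, Sln and Mybphl and at 83376 normalized counts for Nppa. The amount of Nppa per Myl7 in Cre+ replicate 1 was 7.83 times the highest of the controls, so atrial tissue is argued against as the source of its Nppa. In Cre+ replicates 2 to 4 it was at least 5.70 times that of control replicate 3, the control with the most Myl7, but control replicates 1, 2 and 5 were at 122, 5.68 and 13.0 times on the same scale, so for these libraries the share of Nppa from atrial tissue stays open. For Myl7, Myl4, Sln and Mybphl a larger share of atrial tissue remains a candidate explanation, beside an untested induction in ventricular Cre+ muscle. The genes varied together across the 9 libraries. The median SD of their log2 ratio to Myl7 was 0.815, or 0.206 times the SD of 3.96 of log2 Myl7. Induction of the genes together could give the same, so this does not tell these explanations apart. With these markers as a covariate, 227 of 227 called genes outside the atrial list kept their direction. They kept a median of 0.826 of their log2 fold change (quartiles 0.726 and 0.925). These genes had been called on the same libraries, which favours a kept direction and size. Over all 12141 genes, 627 had an unadjusted p under 0.05 with the covariate, against 2687 without it, and 16 passed the threshold. The fit therefore cannot decide how much of the other changes comes from atrial tissue. Calls ended with a smaller fold for Myh7 (from 2.57, SE 0.44, to 1.67, SE 0.40, adjusted p = 0.320) and with a larger error for Cap2 (from -2.22, SE 0.36, to -2.14, SE 0.48, adjusted p = 0.246).

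Control replicate 4, a male, stood apart from the other controls on the first principal component and has Nppa listed at 0. The deviations of the control males 4 and 5 from the same 3 control females had a correlation across autosomal genes of 0.334. This was under the 0.5 set beforehand. In 100 simulations with no sex effect the correlation was 0.194 to 0.300, but the males were drawn with the spread of the females. The real deviations had variances of 1.46 for replicate 4 and 0.454 for replicate 5, so that range cannot be set against 0.334. Their covariance was 0.272, against a simulated 0.0900. The deviation of the Cre+ male from the Cre+ females, which shares no library with these, had a correlation of 0.057 with that of control replicate 4 and of 0.335 with that of control replicate 5, so a part shared between those males is not excluded, but sex is argued against as the whole source for replicate 4. Gene length and GC content accounted for 21.2% of the variance of its deviation, and after their removal the SD of the deviation was still 1.64 times that of the next control, so such a bias is not the whole source. No biological explanation other than sex was tested.

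The mean counts in the authors' deposited table for experiment A were 1.99 times those of the gene rows at the median. For each gene, DESeq2 was run on the sum of its gene, transcript and exon rows. The resulting mean was within 1% of the deposited one for 100% of the 12613 genes with a deposited mean over 100. The share was 0.0872% for the gene rows alone and 87.7% for the gene rows with every count doubled. Doubling alone gave most of the match but not all of it, which argues against doubling as the whole source. The full match of the sums leaves exon reads, entered in addition to the gene counts, as a candidate source. The summed input called 450 genes with DESeq2, 449 of them also called by the authors, and the doubled gene rows 445, with 434. The unfiltered gene rows gave 394, and the authors' deposited table holds 451, with 254 higher and 197 lower. No biological explanation was tested for it.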

How the results depend on the processing

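The fits with the mitochondrial share or the atrial markers as a covariate, the fit on summed rows and the shared counts without 1 library were chosen after seeing the data. The mitochondrial share tended to be lower in Cre+, so as a covariate it can also take up part of the group difference. The count of 220 genes in experiment A was 115 with an absolute log2 fold change of at least 1, 402 with DESeq2, 512 with no filter beyond a count above 0 (30613 genes tested) and 450 with DESeq2 on summed rows, and the last 3 each kept all 220. Leaving out 1 library gave 126 to 275 genes, 9 to 11 lists and Cap2 at -4.38 to -3.93. Of 8 lists, 3 were called by camera with an estimated correlation and 7 by fry, all but the interferon list (fry adjusted p = 0.472). The 228 genes of experiment B became 346 with no filter, 33 with the mitochondrial share and 16 with the atrial markers as a covariate, and 39 to 695 without 1 library. Cap2 was at -2.14 (SE 0.48, adjusted p = 0.246) with the atrial markers and at -2.79 (SE 0.30, adjusted p = 0.00570) with the mitochondrial share. Of 14 lists, 1 held with an estimated correlation, and 14 to 16 were called without 1 library. With fry 3 held, the stress, skeletal muscle and fatty acid oxidation lists (fry adjusted p = 0.000953, 0.00247 and 0.0248). Cap2 stayed between -2.43 and -2.00 without 1 library. The 60 shared genes became 212 at an unadjusted p under 0.01 in both, 144 at an adjusted p under 0.1 and 18 to 95 without 1 library. With the atrial covariate Cap1 turned to -0.16, Sln to -0.70, Mybphl to -0.091 and Bmp10 to -0.68, the covariate being made of Myl7, Myl4, Sln and Mybphl. Myh6, never called, ranged from -0.035 to 0.14 in experiment A and from -0.12 to 0.18 in experiment B without 1 library. No other named gene reversed. Of the named genes of experiment B besides Cap2, 33 lost their call with the atrial covariate, 26 with the mitochondrial share, 7 with females only, 6 after TMM scaling, 4 with no filter, 4 with no sex term, 2 with a minimum mean of 50, 1 after quantile normalization and 1, Abcc9, with the replicate block (adjusted p = 0.0533). In experiment A, RLE size factors, DESeq2 and no filter ended no named call, nor did a minimum mean of 20 among the genes it kept. The block ended those of Acta2 (adjusted p = 0.161), Cnn2 (0.0508), Acaa2 (0.0690), Cpt2 (0.102), Wif1 (0.0822) and Krt18 (0.101). Beyond fewer genes, fewer samples or the covariate itself, the cause was not tested. Replicate numbers did not pair the libraries (correlations of same-numbered deviations -0.17 to -0.021 in experiment A and -0.11 to 0.24 in experiment B, with 0 of 3 and 2 of 4 best with their own number). A replicate block gave 115 higher and 51 lower genes, 10 lists and Cap2 at -4.17 in experiment A, and 394 genes (257 higher and 137 lower) and Cap2 at -2.33 in experiment B. The count test on recovered reads of experiment B was not run, since reads could not be recovered. The 10 splits of experiment A are too few for a share under 0.05. The real one gave 220 genes and the highest other 2 (1 split as high), and 8 lists against 10 (4 splits as high). In experiment B 1 of 100 splits drawn of 126, the real one, gave at least 228 genes, and the highest other gave 79. That argues against chance for the count of genes with all libraries. Without Cre+ replicate 2, however, the real groups gave only 39 genes. For the lists chance cannot be excluded (39 of 100 splits gave at least 14, the highest other 22). Depth limits experiment A to genes above the filter and is unknown in experiment B.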

Other observations

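All genes in this part were chosen after their values were seen. Genes that mark blood and fat differed between libraries within a group. Hbb-bs, an adult beta-globin gene with near-identical paralogs, was at 5872 CPM in CAP2 −/− replicate 1 of experiment A and at 625 to 1890 in the other 5 libraries. In experiment B Hbb-bs ranged from 2262 normalized counts in control replicate 4 to 31211 in control replicate 5. Control replicate 5 also had the most Adipoq (88 normalized counts) and Ucp1 (73), which mark fat cells and brown fat, against at most 42 and 9 in the other libraries. Plin1 (46), Car3 (668) and Adig (19) were highest there too, against at most 18, 285 and 14 in the other libraries. Cidec was at 136 in control replicate 5 and 134 in Cre+ replicate 3. Some fat cell genes were highest elsewhere, among them Cfd in Cre+ replicate 3 (551, against 512 in control replicate 5). Retn was highest in control replicate 3 (40, against 25) and Cidea in Cre+ replicate 2 (214, against 194).

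Bmp10, a gene known for its expression in the right atrium, was at 3 normalized counts in Cre+ replicate 2, where Myl7 was at 6996, and at 4769 and 2491 in Cre+ replicates 3 and 4.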
